A study of Arabidopsis thaliana with 30 samples.

How the data were processed

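RNA was sequenced from whole aerial tissue of 15-day Arabidopsis seedlings of 10 lines, with 3 libraries per line. Per the labels' protocols, seeds were stratified for 3 days at 4 °C and seedlings grew on MS medium with 1% sucrose and 0.8% agar, under 16 h of light at 22 °C and 8 h of dark at 18 °C, with 130 to 150 µmol of light. Per the labels, total RNA was extracted with RNeasy kits and made into Illumina TruSeq libraries at a service facility. The series text places all 10 lines in 1 experiment under the same conditions. The labels call the libraries of the parents and F1 hybrids biological replicates and those of the F6 lines siblings. Whether each came from a separate plant or from a pool is not said, so p-values measure the spread between these samples. The labels give no harvest time and no order of sequencing.

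The deposited gene table holds raw counts, whole numbers per gene model without normalization, per the file headers and the values. Per the submitters' processing notes, FastQC and DESeq were used and the genome build was TAIR10, with no versions or roles. The aligner, the counting tool and the use of strand are not given in the sources used here. The deposited depth table, also in counts of reads, classes the reads of each library as accepted, multiloci or not aligned, and the 3 classes summed to the total reads in all 30 libraries.

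Total reads per library, per the deposited depth table, were 47093898, 45101906 and 45259408 in C24 (A, B and C), 43814602, 46495484 and 45534704 in Ler, 45856620, 46038782 and 47150650 in C24XLer, and 46388088, 52231164 and 52535852 in LerXC24. For siblings 1, 2 and 3 they were 45143518, 42037558 and 45566150 in HM-W, 46411310, 47406126 and 53397900 in HM-S, 42944246, 46841630 and 45156904 in HM-G, 41600826, 43874842 and 44154808 in Med-E, 42539374, 46670142 and 42589302 in Med-F, and 48658690, 45616354 and 45231116 in Sml-D. Accepted reads were 84.6% to 88.9% of these. The gene counts of a library summed to between 46822397 and 60757656, which is 1.29 to 1.32 times its accepted reads, and the reason is not given in the sources used here. Between 31.1% and 32.7% of counts lay in 7139 genes that overlap another counted gene on either strand, and 55 neighbouring entries had identical counts. Such genes are named as overlapping in the report and their values are uncertain. The 10 most abundant genes took 6.54% to 9.05% of a library. The labels list 24 barcodes for the 30 libraries, with 6 used for 2 libraries each, between C24 or Ler and Sml-D or Med-F, and libraries with the same barcode were kept apart as separate samples.

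Of 33498 genes, 1101 had 0 counts in all libraries. Gene identifiers were matched to TAIR10.1 annotation for symbols and positions, with 32742 found and 756 without an entry. The always-named genes lie at chromosome 1 28070295 to 28074177 (ICS1), chromosome 2 6241640 to 6242541 (PR1) and 17886101 to 17889087 (PIF4), chromosome 3 5264001 to 5265695 (IAA19), chromosome 4 14192569 to 14194302 (YUC8) and 15583332 to 15584903 (IAA29), and chromosome 5 3173382 to 3179448 (FLC).

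Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 29268, and TMM factors ran from 0.943 to 1.08. All 30 libraries entered 1 quasi-likelihood fit with 1 coefficient per line (common dispersion 0.0210), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The mid-parent was the mean of the C24 and Ler coefficients on the log scale. A gene was outside the parental range when it was called against both parents in the same direction. The hybrid mimics (HM) were compared with the other F6 lines as 3 against 3 lines, with the 3 sibling libraries of a line summed, because the line is the replicate there, and 29951 genes were tested. A log2 change has its standard error, and levels are CPM, counts scaled to library size with the TMM factors.

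The 23 gene lists covered PIF family, PIF and shade response, auxin biosynthesis, auxin response, brassinosteroid and gibberellin, cell wall expansion, cell cycle, leaf growth regulators, circadian clock, flowering time, floral organ, shoot meristem, epidermal, phloem and root markers, photosynthesis, glucosinolates, flavonoids, salicylic acid and defence, jasmonate, dehydration, heat shock, and senescence with sugar starvation. They were tested with camera at its preset correlation of 0.01 in 11 comparisons, with the 253 tests adjusted together, beside camera with an estimated correlation and fry. The lists, the comparisons, the naming rule and the alternatives were fixed before the data were examined, apart from those named below as added later. The text names, for C24 against Ler, the F1 against the mid-parent and the mimics against the other F6 lines, the 5 genes with the largest rise and the 5 with the largest fall. These had to be called, to average at least 10 CPM, to have no overlap between the libraries of the 2 sides, and in the F1 to lie outside the parental range. For the mimics overlap was read from the summed lines; read from single libraries, AT1G47400 would give way to AT5G24660 (-3.36). It also names up to 3 members with the smallest adjusted p in the 5 lists with the smallest camera p, and always PIF4, YUC8, IAA19, IAA29, PR1, ICS1 and FLC. For single F6 lines these 7 and the list members named for the F1 are given, and any other gene in the text was chosen after its values were seen.

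Parental levels in the F6 lines were read from the 324 genes called between the parents with an absolute log2 change of at least 3, as a position from Ler (0) to C24 (1) with bounds of 0.25 and 0.75. A local parental class of each gene was taken from 4 such genes on each side, with 6 of 8 needed, and in a second setting from 663 genes with a log2 change of at least 2, with 3 on each side and 5 of 6 needed. Overlaps outside the parental range were set beside 8 simulated data sets in which no gene lay outside it. The mean of F1 against the mid-parent, the clock index and the local classes were added after the data had been seen.

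Alternatives were RLE factors, the Wald test of DESeq2 1.42.0, no filter, a filter of 5 CPM in 3 libraries, only the compared lines in the fit, each library or line left out, a block of replicate letters or sibling numbers, the 18 siblings as replicates, an arithmetic mid-parent, and other bounds and marker minima. The clock index as a covariate and LerXC24 libraries thinned to the depth of C24XLer were added later. The arithmetic mid-parent averaged scaled C24 and Ler libraries of the same letter into 3 libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6.

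The tests were tried on simulated counts with 200 changed genes. At 1.5-fold, 2-fold and 4-fold changes the comparison of C24 with Ler found 52.2%, 86.6% and 98.5% with 10 false calls, that of HM-W with the mid-parent 70.1%, 89.6% and 98.5% with 7, and that of 3 against 3 lines 0%, 28.4% and 98.5% with 7. The last comparison therefore misses most changes of 2-fold or less. No library was left out of the main results.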

Results

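The 30 libraries came from whole aerial tissue of 15-day Arabidopsis thaliana seedlings, with 3 libraries for each of 10 lines. The lines were the parents C24 and Ler, the reciprocal F1 hybrids C24XLer and LerXC24, and 6 F6 lines from the same cross. HM-W, HM-S and HM-G are named hybrid mimics in the labels, and Med-E, Med-F and Sml-D are the other F6 lines. Per the deposited alignment summaries each library held between 41600826 and 53397900 reads, and 29268 of 33498 genes had enough counts to be tested. Pairs of libraries of the same line correlated at 0.983 to 0.993, and pairs from different lines at 0.953 to 0.992.

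C24 and Ler differed strongly at single genes of glucosinolate metabolism, flowering and arginine breakdown. AOP2, which makes alkenyl glucosinolates, was at 783 ± 114 CPM (counts scaled to library size, mean ± SD of 3 libraries, the form used throughout for levels) in C24 and 2.69 ± 0.53 in Ler, and AOP3, which makes hydroxyalkyl glucosinolates, was at 1.15 ± 0.26 and 218 ± 54. The myrosinase gene TGG2 was higher in C24 by a log2 change of 7.53 ± 0.18 (± standard error throughout, adjusted p = 6.9e-20), and the arginase gene ARGAH2 was lower by -9.09 ± 0.67. The floral repressor FLC was at 93.9 ± 6.8 in C24 and 0.90 ± 0.17 in Ler, a log2 change of 6.71 ± 0.21 (adjusted p = 5.4e-18). The other largest differences were AT1G35115 (9.59 ± 0.26), AT2G25510 (9.03), AT4G04692 (8.39) and AT3G61010 (8.39 ± 0.98) above Ler, and AT2G24760 (-7.47, a gene that overlaps another counted gene), ECS1 (-7.24 ± 0.64) and AT3G44070 (-6.49) below it. In all, 3902 genes were higher and 3653 lower in C24 at an adjusted p under 0.05, and 10548 genes had an unadjusted p under 0.05.

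Glucosinolate genes were higher in C24: 13 of 27 measured members rose and 2 fell (14 and 2 when adjusted over the list alone), among them MAM1 (2.74 ± 0.18), CYP79F1 (1.56 ± 0.39) and MYB29 (1.46 ± 0.41). The list test gave an adjusted p of 2.9e-07, and an adjusted p = 0.666 with an estimated correlation. Abscisic acid and dehydration genes were lower in C24, with 12 of 24 members falling and 0 rising (13 and 0 over the list alone). RD29A changed by -3.04 ± 0.46, KIN2 by -1.91 ± 0.27 and KIN1 by -1.79 ± 0.27, the last 2 being close copies whose reads are hard to separate. That list gave 6.8e-05, and an adjusted p = 0.666 with an estimated correlation. Floral organ genes fell at 7 of 8 members over all genes and over the list alone, with SEP3 at -2.35 ± 0.26, AP3 at -2.15 ± 0.33 and AP1 at -1.95 ± 0.38 (list adjusted p = 6.8e-04, adjusted p = 0.666 with an estimated correlation). Flowering-time genes changed in both directions, 7 up and 4 down of 22 on both counts, with SOC1 at -2.97 ± 0.19 and FUL at -2.15 ± 0.20 (list adjusted p = 0.535).

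Cell-cycle genes were lower in C24 at 12 of 25 members and higher at 1 (14 and 2 over the list alone), with KNOLLE at -0.94 ± 0.12, AUR2 at -0.84 ± 0.09 and CYCB1;4 at -0.82 ± 0.12. KNOLLE and AUR2 overlap other counted genes and are uncertain. The list gave 0.0018, and an adjusted p = 0.666 with an estimated correlation. Root markers were higher at 6 of 12 members on both counts, including PYK10 (2.00 ± 0.30), EXPA18 (2.14 ± 0.45) and EXPA7 (1.00 ± 0.22), all 3 overlapping another gene (list adjusted p = 0.041, adjusted p = 0.708 with an estimated correlation). Only aerial tissue was sampled per the labels, and the source of these reads was not tested. Heat-shock genes fell at 7 of 12 members and rose at 0 (8 and 0 alone), epidermal markers at 4 of 12 with 1 rising (6 and 1 alone), and phloem markers at 2 of 4 with 0 rising (3 and 0 alone), with list adjusted p of 0.082, 0.276 and 0.246. Ler C stood apart at heat-shock genes, with HSP17.6II at 16.2 and HSP17.6C at 9.26 beside 0.75 and 0.93 in Ler A and 3.12 and 1.65 in Ler B.

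The auxin genes were not called as a group between the parents: 6 of 31 auxin-response genes were higher in C24 and 7 lower (6 and 8 alone, list adjusted p = 0.992, median 0.05, mean -0.08). IAA7 was higher at 1.32 ± 0.13, and IAA19 was lower at -0.45 ± 0.11 (adjusted p = 0.0048). In auxin biosynthesis 3 of 13 members fell and 0 rose on both counts, with YUC4 at -0.86 ± 0.16 and TAA1 at -0.79 ± 0.15, while YUC8 was at 0.20 ± 0.30 (adjusted p = 0.683). PIF4, a light- and temperature-controlled factor that activates YUC8 and IAA29, was higher in C24 by 0.51 ± 0.14 (adjusted p = 0.0067), but the call ended without library C24 C (0.34, adjusted p = 0.087) and with the clock index described below in the fit (0.19, adjusted p = 0.325). IAA29 was at 0.65 ± 0.28 (adjusted p = 0.093), the salicylic acid synthesis gene ICS1 at 0.33 (adjusted p = 0.084) and PR1, a salicylic acid response gene, at -2.22 ± 1.16 (adjusted p = 0.173). The call of ICS1 passed without library Ler B (0.45, adjusted p = 0.040) and with the clock index in the fit (0.46, adjusted p = 0.045).

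The libraries also differed in the balance of morning and evening clock genes. A clock index, the mean of evening genes such as TOC1 and LUX minus the mean of morning genes such as PRR9, LNK1 and RVE8, was -0.72 (SD 0.74) in C24, -1.65 (0.28) in Ler, -1.12 (0.34) in C24XLer and 0.07 (0.71) in LerXC24. It was -0.04 (0.23) in HM-W, -0.14 (0.09) in HM-S, -0.60 (0.15) in HM-G, -2.07 (0.33) in Med-E, -0.47 (0.20) in Med-F and -1.86 (0.13) in Sml-D. The 15 genes of the index were chosen after the data had been seen. The index correlated with the first principal component of all 30 libraries at r = 0.922, and that component held 24.04% of the variance. Within lines, 2076 genes changed with the index, 1046 rising and 1030 falling, PIF4 among them with a slope of 0.32 (adjusted p = 0.0070) and YUC8 with 0.74 (adjusted p = 0.0034). IAA29 had a slope of 0.49 (adjusted p = 0.10) and IAA19 of -0.01. The time of harvest is not given in the labels.

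**Figure D1:**
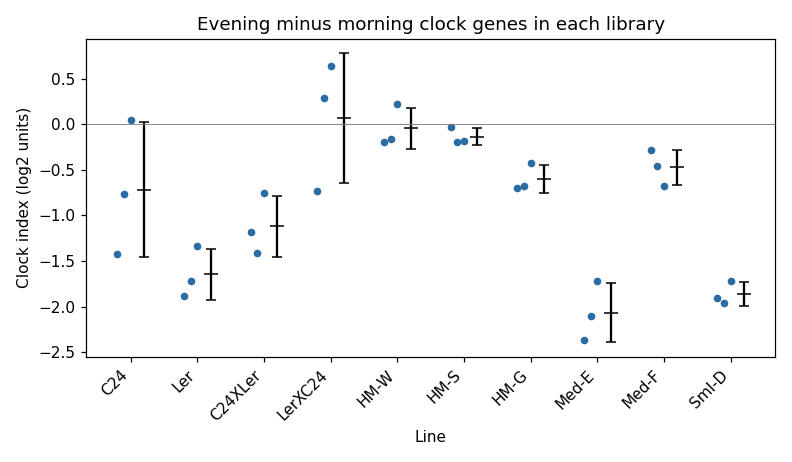
Clock index of the 30 libraries by line. Med-E had the lowest mean (-2.07) and LerXC24 the highest (0.07).

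Against the mean of the parents on the log scale, the 2 F1 hybrids together gave their largest rises, among genes outside the parental range, of at least 10 CPM and without overlap of F1 and parent libraries, at AT3G22121 (1.17 ± 0.17) and CWLP (1.08 ± 0.13), which overlap each other, BEE1, AT2G41178 (0.71, overlapping another gene) and NSH3 (0.68 ± 0.12). The brassinosteroid-responsive factor BEE1 rose by 0.93 ± 0.13 (adjusted p = 5.3e-05). ST2A, a jasmonate sulfotransferase, rose by 1.71 ± 0.25 (adjusted p = 8.6e-05) and IAA29 by 1.04 ± 0.20 (adjusted p = 0.0018). YUC8 rose by 0.65 ± 0.21 (adjusted p = 0.046) and PIF4 by 0.34 ± 0.10 (adjusted p = 0.024). YUC8 was at 2.59 in C24XLer, near C24 (2.48), and 5.02 in LerXC24. GOLS3, a raffinose-pathway gene, fell by -0.87 ± 0.15 and GAPA-2, a chloroplast Calvin-cycle gene, by -0.61 ± 0.11 (adjusted p = 8.7e-04), with AT1G79075 at -0.76, AT3G18280 at -0.65 and AT2G40205 at -0.63 (overlapping). Against an arithmetic mid-parent the calls of AT2G41178 (adjusted p = 0.091) and AT2G40205 (adjusted p = 0.092) ended, the latter also with the clock index (-0.59, adjusted p = 0.070). In total 2077 genes were higher and 1301 lower than the mid-parent, 8162 had an unadjusted p under 0.05, and 39.0% of the calls lay at genes that differed between the parents. For F1 versus mid-parent the total was 1888 without C24XLer B and 4964 without C24XLer A. With the clock index in the fit it was 1131, and against an arithmetic mid-parent 371.

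The calls of PIF4 and YUC8 ended under several alternatives. With the clock index in the fit PIF4 was at 0.14 (adjusted p = 0.376), YUC8 at 0.18 (adjusted p = 0.625) and IAA29 at 0.70 (adjusted p = 0.060). PIF4 was not called without C24 A (0.27, adjusted p = 0.072), C24 B, Ler B, C24XLer B (0.30, adjusted p = 0.075), LerXC24 B or LerXC24 C. YUC8 was not called without C24 A (0.53, adjusted p = 0.119), C24 B, Ler A, Ler B, C24XLer B, C24XLer C, LerXC24 B (0.52, adjusted p = 0.133) or LerXC24 C. Against an arithmetic mid-parent PIF4 was at 0.33 (adjusted p = 0.126) and YUC8 at 0.65 (adjusted p = 0.154). IAA19 was at 0.10 (adjusted p = 0.44) and ICS1 at 0.05 (adjusted p = 0.795).

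The auxin, shade and growth lists did not pass as groups in the F1. In the PIF and shade list 4 of 15 members rose and 0 fell on both counts, with PIL1 at 0.64 ± 0.17 and CKX5 at 0.44 ± 0.07 (list adjusted p = 0.110). In the PIF family 1 of 5 rose on both counts, PIF4 alone. In auxin biosynthesis YUC2 (0.59 ± 0.16), YUC5 (0.44 ± 0.12) and YUC8 rose and TAA1 fell (-0.41 ± 0.11), 3 and 1 of 13 (3 and 2 alone). Auxin-response genes moved both ways, 3 of 31 up and 4 down (5 and 6 alone), with IAA7 at 0.52 ± 0.09, GH3.2 at -0.92 ± 0.15 and GH3.5 at -0.61 ± 0.13. Cell-wall genes XTH4 (0.63 ± 0.19), XTH8 (0.61 ± 0.17) and XTH17 (0.61 ± 0.19) rose, 3 of 23 with 0 falling (3 and 1 alone). Leaf growth regulators rose at 2 of 8, TCP4 (0.45 ± 0.07) and GRF3 (0.35 ± 0.09), and 0 fell (4 and 0 alone). In the brassinosteroid and gibberellin list 2 of 19 rose and 0 fell (3 and 0 alone), CPD at 0.42 ± 0.13 and BZR1 at 0.19 ± 0.05. Circadian genes rose at 3 of 20 with 0 falling (5 and 7 alone), led by LUX at 0.54 ± 0.13.

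Of 32 photosynthesis genes 6 fell in the F1 and 2 rose (9 and 2 alone), LHCB3 by -0.48 ± 0.10 and LHCB6 by -0.44 ± 0.11, both overlapping other genes. C24XLer A stood apart at the parental level, with LHCB3 at 6535 and LHCB6 at 3371 CPM beside at most 4969 and 2313 in the other 5 F1 libraries. PSAD1 was 1 of the 2 that rose (0.29 ± 0.07), and was not called without C24XLer B (0.22, adjusted p = 0.053). The list had an adjusted p of 0.0012, and an adjusted p = 0.879 with an estimated correlation. The calls of LHCB3 (-0.40, adjusted p = 0.065) and LHCB6 (-0.37, adjusted p = 0.115) ended with the clock index in the fit, and also against an arithmetic mid-parent.

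Genes of the flower and the shoot meristem were lower in the F1 as well. PI (-0.36 ± 0.10), SEP1 (-0.59 ± 0.16, overlapping) and AP1 (-0.96 ± 0.28) fell, 3 of 8 floral organ genes with 0 rising (6 and 0 alone, list adjusted p = 0.0018, adjusted p = 0.666 with an estimated correlation). KNAT2 (-0.49 ± 0.13) and STM (-0.97 ± 0.31) fell, 2 of 7 meristem genes with 0 rising (4 and 0 alone). The list adjusted p was 0.026, and 0.666 with an estimated correlation. WUS was at -0.58 (adjusted p = 0.052). Single libraries ended these calls: without Ler A, PI was at -0.28 (adjusted p = 0.065), AP1 at -0.78 (adjusted p = 0.083), KNAT2 at -0.40 (adjusted p = 0.064) and STM at -0.91 (adjusted p = 0.089), and without C24 A SEP1 was at -0.48 (adjusted p = 0.078). WUS passed without C24XLer A (-0.69, adjusted p = 0.022). All 5 calls ended with the clock index in the fit, with AP1 at -0.86 (adjusted p = 0.163) and STM at -0.98 (adjusted p = 0.140), and against an arithmetic mid-parent all but AP1 ended. STM was at 0.86 in C24XLer A, 1.02 in LerXC24 C and 2.83 in LerXC24 A, and at 4.56 to 4.66 in the other 3 F1 libraries, within the C24 range of 3.33 to 6.21. SOC1 (-0.58 ± 0.13) and FUL (-0.91 ± 0.14) fell among flowering-time genes, 4 of 22 falling and 3 rising (4 and 5 alone, list adjusted p = 0.857).

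PR1 fell in the F1 by -3.25 ± 0.88 (adjusted p = 0.019), from 22.9 ± 2.8 in C24 and 107 ± 59 in Ler to 7.45 ± 5.0 in C24XLer and 3.61 ± 1.2 in LerXC24. The call of PR1 in F1 versus mid-parent ended without C24XLer B (-3.02, adjusted p = 0.057), without LerXC24 B (-3.14, adjusted p = 0.053) and against an arithmetic mid-parent (-3.63, adjusted p = 0.066). PBS3 (-0.67 ± 0.15) was the only other salicylic acid gene that fell, 2 of 30 with 0 rising on both counts. Of 12 heat-shock genes only HSP22 fell (-0.99 ± 0.30, adjusted p = 0.037), and 0 rose (2 and 0 alone), with HSP21 at -0.61 (adjusted p = 0.057) and HSP17.6C at -1.09 (adjusted p = 0.128). That list had an adjusted p of 0.035, and an adjusted p = 0.884 with an estimated correlation. The HSP22 call ended without 7 of the 12 libraries, with -0.65 (adjusted p = 0.139) without Ler C, and against an arithmetic mid-parent (adjusted p = 0.094). HSP21 was called by DESeq2 (-0.61, adjusted p = 0.043). In the remaining lists the F1 gave 2 of 24 jasmonate genes up and 0 down (0 and 0 alone), 2 of 18 flavonoid genes up and 0 down (3 and 0 alone), 2 of 24 dehydration genes up and 1 down (2 and 2 alone) and 1 of 16 senescence genes up with 2 down (2 and 2 alone). Cell-cycle genes gave 3 of 25 up and 2 down (4 and 5 alone), epidermal markers 2 of 12 up and 1 down (3 and 1 alone), and root and phloem markers 0 of 12 and 0 of 4.

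Genes that 1 parent hardly expressed sat near the higher parent on the log scale. TGG2 rose by 2.68 ± 0.10, AOP2 by 2.32 ± 0.13, AOP3 by 3.19 ± 0.18 and FLC by 2.43 ± 0.13 against the log mid-parent. Against the arithmetic mid-parent they were at -0.08, -0.77, 0.41 and 0.07, so the direction turned for TGG2 and AOP2 and only AOP2 passed (adjusted p = 0.013). FLC was at 49.2 ± 5.8 in C24XLer and 49.5 ± 6.9 in LerXC24. These 3 side-chain and myrosinase genes were all the glucosinolate calls in the F1, 3 of 27 with 0 falling (4 and 0 alone). The list median was -0.10 while its mean was 0.24 and its test pointed up (adjusted p = 0.0025, adjusted p = 0.879 with an estimated correlation).

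Taken singly, the reciprocal hybrids gave unequal numbers of calls. C24XLer had 550 genes above and 135 below the mid-parent, with 5310 unadjusted, and LerXC24 had 2969 above and 1851 below, with 9113 unadjusted. The total of C24XLer versus mid-parent was 256 without C24XLer B and 2007 without C24XLer A, 1158 by DESeq2, 290 with only the compared lines in the fit and 13 against an arithmetic mid-parent. The total of LerXC24 versus mid-parent was 1307 without LerXC24 C. With the clock index in the fit the order turned, with 159 in LerXC24 and 1020 in C24XLer. In LerXC24 YUC2 (1.04 ± 0.19), YUC5 (0.69 ± 0.14), YUC8 (1.13 ± 0.24), IAA29 (1.38 ± 0.23) and PIF4 (0.47 ± 0.12) rose. Of the clock genes LUX rose (0.92 ± 0.15) and PRR9 (-1.74 ± 0.45), LNK1 (-1.25 ± 0.27) and RVE8 (-0.84 ± 0.24) fell, all 4 being part of the clock index, so that their change and its high value here are the same observation. Of the list 4 of 20 were rising and 8 falling (6 and 8 alone, list adjusted p = 0.530).

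The dehydration list pointed opposite ways in the 2 crosses. In LerXC24 dehydration genes fell at 9 of 24 members with 0 rising (10 and 0 alone), NCED3 by -1.41 ± 0.37 and P5CS1 by -1.09 ± 0.22 (list adjusted p = 2.3e-04, adjusted p = 0.666 with an estimated correlation). In C24XLer 1 rose and 1 fell (5 and 1 alone), and the list pointed up (adjusted p = 0.0012, adjusted p = 0.708 with an estimated correlation). C24XLer was also higher at 4 of 18 flavonoid genes, including UGT75C1 (1.09 ± 0.22) and AACT1 (1.03 ± 0.20), with 0 lower (10 and 0 alone, list adjusted p = 1.6e-06, adjusted p = 0.666 with an estimated correlation). Its glucosinolate list rose at 4 of 27 with 0 falling (6 and 0 alone, list adjusted p = 2.3e-15, adjusted p = 0.666 with an estimated correlation). Of 24 jasmonate genes 0 passed over all genes and 10 rose over the list alone (list adjusted p = 3.4e-05, adjusted p = 0.666 with an estimated correlation). In LerXC24 these 3 lists were not called: 0 flavonoid genes rose and 1 fell (0 and 0 alone, list adjusted p = 0.189), 4 glucosinolate genes rose and 5 fell (4 and 11 alone, list adjusted p = 0.911), and 1 jasmonate gene rose with 0 falling (0 and 0 alone, list adjusted p = 0.389).

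Compared directly, C24XLer was higher than LerXC24 at 6 of 24 jasmonate genes (13 over the list alone), 13 of 24 dehydration genes (16 alone), 4 of 18 flavonoid genes (12 alone) and 6 of 27 glucosinolate genes (19 alone), each with 0 lower on both counts, and at 3 of 23 cell-wall genes with 7 lower (5 and 9 alone). No list test was run for this comparison. The jasmonate regulator MYC2 differed by 1.89 ± 0.47 and the dehydration gene RD26 by 2.16 ± 0.49. XTH8 (-1.33 ± 0.24) and YUC2 (-0.89 ± 0.22) were lower. YUC8 was at -0.96 ± 0.29 (adjusted p = 0.055), IAA29 at -0.67 ± 0.27 (adjusted p = 0.164) and PIF4 at -0.26 (adjusted p = 0.315), and FLC was at -0.01. In all 687 genes were higher and 752 lower, with 5639 unadjusted, and 0 of 86 chloroplast genes and 2 of 22 mitochondrial genes were among them.

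That count of 1439 for C24XLer versus LerXC24 depended on the fit and on single libraries. With only the 6 hybrid libraries in the fit edgeR called 0 genes, with 3917 at an unadjusted p under 0.05, whereas DESeq2 in the fit of all lines called 2156. With the clock index in the fit edgeR called 0, with 841 unadjusted. Without LerXC24 C the count was 0, and without LerXC24 A it was 2944.

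In the hybrid mimics, the auxin genes YUC8 and IAA29 were higher than in the other F6 lines. YUC8 was at 5.48 ± 0.32, 6.42 ± 1.2 and 5.65 ± 1.4 CPM in HM-W, HM-S and HM-G, beside 1.54 ± 0.25, 2.09 ± 0.59 and 2.09 ± 0.32 in Med-E, Med-F and Sml-D, a log2 change of 1.62 ± 0.16 between 3 and 3 lines (adjusted p = 0.014). IAA29, an early auxin and PIF target, was at 32.4 ± 11, 34.3 ± 13 and 33.9 ± 1.9 against 2.91 ± 0.17, 8.42 ± 2.3 and 7.25 ± 1.9, a change of 2.43 ± 0.37 (adjusted p = 0.040). PIF4 was at 0.62 ± 0.21 (adjusted p = 0.186). Its level was 178 ± 5.3 in Med-F, near the mimics at 186 to 211, and 107 ± 20 and 108 ± 12 in Med-E and Sml-D. PIF4 passed without Med-F (0.90, adjusted p = 0.0083) and with the 18 siblings as replicates (0.63, adjusted p = 0.0014). IAA19 was at 0.47 ± 0.37 (adjusted p = 0.525), ICS1 at -0.08 (adjusted p = 0.77), PR1 at 1.83 ± 0.96 (adjusted p = 0.345) and FLC at 0.52 ± 1.02 (adjusted p = 0.812), FLC passing without Med-E (2.95, adjusted p = 0.0058).

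Leaving out 1 line ended auxin calls at similar changes. YUC8 was not called without HM-W (1.66, adjusted p = 0.077), HM-S (1.55, adjusted p = 0.078) or Sml-D (1.69, adjusted p = 0.058), and IAA29 was not called without HM-W (2.46, adjusted p = 0.146), HM-S (2.41, adjusted p = 0.148), HM-G (2.42, adjusted p = 0.074) or Sml-D (2.56, adjusted p = 0.130). The clock index was -0.60 to -0.04 in the mimics, with Med-F (-0.47) within that range and Med-E (-2.07) and Sml-D (-1.86) below it. With the index as a covariate of the 6 lines YUC8 was at 1.44 (adjusted p = 0.138), IAA29 at 1.89 (adjusted p = 0.246) and PIF4 at 0.16 (adjusted p = 0.73). The fit of 30 libraries takes its error from siblings, not lines. In it the index took IAA29 from 2.57 to 2.00, YUC8 from 1.63 to 0.74 and PIF4 from 0.66 to 0.28. Between HM-G and Med-F, whose indices were -0.60 and -0.47, IAA29 differed by 2.01 ± 0.28 (adjusted p = 1.4e-05), YUC8 by 1.44 ± 0.30 (adjusted p = 0.0010) and PIF4 by 0.21 (adjusted p = 0.286).

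**Figure D2:**
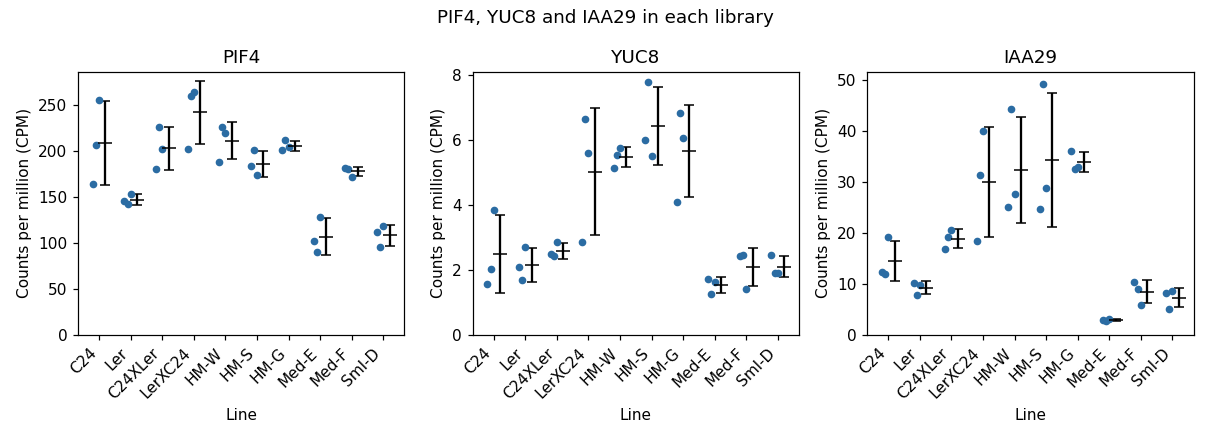
CPM of PIF4, YUC8 and IAA29 in each library of the 10 lines. IAA29 was at 33.9 in HM-G and 2.91 in Med-E.

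The genes with the largest differences between mimics and other F6 lines were not auxin genes. AT2G15042 (6.36 ± 0.42) and RLP18 (5.21 ± 0.40), both leucine-rich-repeat receptor genes, were higher in the mimics, with CYP71B22 (2.77 ± 0.31), AT2G16660 (2.68 ± 0.17) and the dark- and sugar-starvation gene SEN1 (2.62 ± 0.20). The paired immune receptor genes DAR4 (-4.28 ± 0.15, adjusted p = 2.0e-04) and CSA1 (-3.97 ± 0.13, adjusted p = 2.0e-04) were lower, and so were AT1G50290 (-5.35 ± 0.32), the sulfur-deficiency gene ATSDI1 (-4.27 ± 0.55) and the iron-deficiency gene AT1G47400 (-3.51). In all 241 genes were higher and 203 lower, 132 and 105 of them at least 2-fold, with 5962 unadjusted. The count of HM lines versus other F6 lines was 33 without HM-S and 2373 without Med-F, 2965 by DESeq2, 53 with the clock index and 8716 with siblings as replicates.

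Flavonoid genes were lower in the mimics and heat-shock genes higher. PAP1, the main anthocyanin activator, fell by -2.59 ± 0.33 (adjusted p = 0.025) and FLS1 by -1.39 ± 0.18 (adjusted p = 0.026), 2 of 18 with 0 rising (12 and 0 alone), and CHS was at -1.19 (adjusted p = 0.051, overlapping). The list median was -1.15 and its adjusted p 2.1e-11, with an adjusted p = 0.666 with an estimated correlation. Among heat-shock genes HSP17.6II (2.90 ± 0.25), HSP17.4 (2.08 ± 0.21, overlapping), HSP17.6C (2.04 ± 0.21) and HSP23.6 (0.80 ± 0.12) rose, 4 of 12 with 0 falling (9 and 1 alone, list adjusted p = 4.3e-09, adjusted p = 0.666 with an estimated correlation). Leaving out lines ended several calls, among them that of PAP1 in HM lines versus other F6 lines. Without HM-S PAP1 was at -2.56 (adjusted p = 0.126), FLS1 at -1.39 (adjusted p = 0.124), HSP17.6II at 2.92 (adjusted p = 0.063), HSP17.4 at 2.07 (adjusted p = 0.079) and HSP17.6C at 1.89 (adjusted p = 0.071). CHS passed without Med-F (-1.31, adjusted p = 0.021). Siblings differed, with HSP17.6II at 10.1, 11.3 and 1.75 in HM-S and 8.28, 7.31 and 3.32 in HM-W.

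Cell-wall genes XTH8 (1.13 ± 0.16) and XTH30 (0.99 ± 0.11) rose in the mimics, 2 of 23 with 0 falling (6 and 3 alone, list adjusted p = 0.033, adjusted p = 0.666 with an estimated correlation), and XTH19 was at 1.74 (adjusted p = 0.070). Both calls ended without HM-W (XTH8 1.04, adjusted p = 0.138, and XTH30 1.00, adjusted p = 0.101), and XTH19 passed without Med-F (1.47, adjusted p = 0.032). Of 31 auxin-response genes IAA2 (0.90 ± 0.14), IAA29, SAUR20 (0.98 ± 0.14) and SAUR24 (1.34 ± 0.13) rose and 0 fell (5 and 0 alone, list adjusted p = 0.063), and the SAUR genes are close copies. ST2A (1.83 ± 0.28) was the only PIF and shade gene called, and YUC8 the only 1 of 13 auxin-biosynthesis genes, with 0 of 5 in the PIF family. Glucosinolate genes fell at 1 of 27, MYB34 (-0.9997 ± 0.15), with 0 rising (4 and 0 alone, list adjusted p = 0.0041, adjusted p = 0.884 with an estimated correlation). MYB34 was not called without HM-W (-1.06, adjusted p = 0.138), and GSTF11 (-1.298, adjusted p = 0.084) passed without Med-F (-1.56, adjusted p = 0.0054). MYB29 in HM lines versus other F6 lines (-2.67, adjusted p = 0.099) passed without it as well (-3.13, adjusted p = 0.0018).

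Floral organ genes gave 0 calls of 8 with edgeR over all genes (0 up and 3 down alone, list adjusted p = 0.0026, adjusted p = 0.708 with an estimated correlation). LFY was at -0.66 (adjusted p = 0.070), AP1 at -1.88 (adjusted p = 0.112) and SEP1 at -1.32 (adjusted p = 0.133), all 3 called by DESeq2, and AP1 (-2.26, adjusted p = 0.035) and SEP1 (-1.64, adjusted p = 0.026) passed without Med-E. Among the rest, COR47 rose (1.49 ± 0.20) and HAB1 fell (-1.10 ± 0.17), 1 and 1 of 24 dehydration genes (2 and 2 alone), SEN1 rose and SAG113 fell (-2.47 ± 0.40), 1 and 1 of 17 senescence genes (2 and 2 alone), and KNOLLE (0.56 ± 0.09) was 1 of 25 cell-cycle genes. KAT1 (0.86 ± 0.13) was called among 12 epidermal markers and SWEET12 (0.85 ± 0.11) among 4 phloem markers. None was called among 20 circadian, 22 flowering-time, 19 brassinosteroid and gibberellin, 8 leaf growth, 32 photosynthesis, 30 salicylic acid, 24 jasmonate, 12 root and 7 meristem genes. Over the list alone, flowering-time genes gave 1 up and 5 down, circadian genes 0 and 2 and brassinosteroid and gibberellin genes 2 and 0.

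Each of the 3 mimics held YUC8 and IAA29 above the mid-parent. YUC8 rose by 1.25 ± 0.24 in HM-W (adjusted p = 6.3e-04), 1.48 ± 0.24 in HM-S (adjusted p = 8.6e-05) and 1.29 ± 0.24 in HM-G (adjusted p = 7.6e-04), and IAA29 by 1.48 ± 0.23, 1.57 ± 0.23 and 1.55 ± 0.23. PIF4 was at 0.27 (adjusted p = 0.093), 0.09 and 0.23, and passed in HM-W without C24 C (0.36, adjusted p = 0.018). IAA19 rose in HM-S (0.52 ± 0.10) and HM-G (0.84 ± 0.10) and was at 0.09 in HM-W. With the clock index in the fit the HM-W calls ended, YUC8 at 0.46 (adjusted p = 0.332) and IAA29 at 0.95 (adjusted p = 0.055). In Med-E IAA29 fell by -1.99 ± 0.28 (adjusted p = 1.8e-05), PIF4 by -0.71 ± 0.12 and PIF5 by -0.44 ± 0.08. Med-F and Sml-D had IAA29 at -0.46 (adjusted p = 0.19) and -0.67 (adjusted p = 0.077), YUC8 at -0.14 in both, and PIF4 at 0.02 in Med-F and lower by -0.69 ± 0.12 in Sml-D. With the clock index in the fit IAA29 passed in Med-F (-0.81, adjusted p = 0.033), and with DESeq2 it passed in Sml-D (-0.68, adjusted p = 0.035). IAA19 rose in Sml-D (0.71 ± 0.10, adjusted p = 1.1e-05) and fell in Med-F (-0.58 ± 0.10) and Med-E (-0.34 ± 0.10, adjusted p = 0.025). The Med-E call ended without Ler A, Ler C, Med-E 1 or Med-E 2 (-0.24, adjusted p = 0.213), with the clock index (-0.35, adjusted p = 0.109) and against an arithmetic mid-parent (-0.34, adjusted p = 0.061).

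HM-W and HM-S shared further changes against the mid-parent. Dehydration genes fell at 17 of 24 members in HM-W with 0 rising on both counts (list adjusted p = 4.6e-08) and at 14 with 1 rising on both counts in HM-S (1.6e-04), each at an adjusted p = 0.666 with an estimated correlation, P5CS1 falling by -1.47 ± 0.22 and -1.42 ± 0.22. Photosynthesis genes fell at 15 of 32 members in HM-W (17 alone, list adjusted p = 1.8e-04, adjusted p = 0.806 with an estimated correlation) and 23 in HM-S (24 alone, 2.9e-07, adjusted p = 0.666 with an estimated correlation), with 0 rising. LHCB3 was at -0.60 ± 0.13 and -0.65 ± 0.13. The HM-W call of LHCB3 ended with the clock index in the fit (-0.47, adjusted p = 0.129). The brassinosteroid synthesis gene BR6OX2 rose in both, by 1.45 ± 0.24 and 1.79 ± 0.24, and so did XTH4 (1.56 ± 0.23 and 1.44 ± 0.23). The cell-wall list rose in HM-W at 8 of 23 with 2 falling (9 and 2 alone, list adjusted p = 0.032, adjusted p = 0.666 with an estimated correlation). In HM-S the PIF and shade list rose at 5 of 15 with 1 falling (0.0496) and the circadian list fell at 9 of 20 with 2 rising (0.033), both the same alone and both at an adjusted p = 0.666 with an estimated correlation.

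In HM-G heat-shock and auxin-response genes were higher than the mid-parent, and a difference between the mimics was not tested. HM-G had 7 of 12 heat-shock genes up and 0 down (8 and 0 alone), HSP90.1 by 2.19 ± 0.46 (list adjusted p = 5.9e-04, adjusted p = 0.666 with an estimated correlation). Auxin-response genes rose at 8 of 31 with 1 falling (12 and 1 alone) (list adjusted p = 0.0092, adjusted p = 0.666 with an estimated correlation). Cell-wall genes rose at 7 of 23 with 0 falling on both counts, XTH19 by 1.65 ± 0.31 (list adjusted p = 0.048, adjusted p = 0.666 with an estimated correlation), and ARGOS by 1.303 ± 0.18. Flavonoid genes fell at 4 of 18 with 0 rising on both counts, CHI by -0.95 ± 0.24 (list adjusted p = 0.0045, adjusted p = 0.874 with an estimated correlation), and LHCB3 was at 0.02 (adjusted p = 0.946).

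Med-E fell at 5 of 16 senescence and sugar-starvation genes with 0 rising on both counts, ASN1 by -4.09 ± 0.58 (list adjusted p = 0.0021), and at 3 of 5 PIF genes with 0 rising on both counts (0.0034), both lists at an adjusted p = 0.666 with an estimated correlation. Its flowering-time list rose at 8 of 22 with 2 falling (9 and 4 alone, 0.0125) and its auxin-response list fell at 8 of 31 with 2 rising (8 and 3 alone, 0.037), both at an adjusted p = 0.666 with an estimated correlation. Med-F rose at 6 of 8 floral organ genes with 0 falling (7 and 0 alone), AP3 by 1.84 ± 0.25 (list adjusted p = 2.1e-05, adjusted p = 0.666 with an estimated correlation). Med-F fell at 17 of 27 glucosinolate genes with 2 rising (18 and 2 alone, list adjusted p = 1.8e-04, adjusted p = 0.708 with an estimated correlation). It also fell at 16 of 24 dehydration genes with 1 rising (18 and 1 alone, 5.7e-08) and 13 of 32 photosynthesis genes with 0 rising (19 and 0 alone, 2.0e-07), both at an adjusted p = 0.666 with an estimated correlation. Sml-D rose at 15 of 18 flavonoid genes with 0 falling (16 and 0 alone), PAP1 by 1.60 ± 0.38 (list adjusted p = 5.1e-11, adjusted p = 0.666 with an estimated correlation). For PR1 in Sml-D versus mid-parent the fall was -4.82 ± 1.32 (adjusted p = 0.015), which ended without Sml-D 1 (-4.32, adjusted p = 0.079) or Sml-D 2 (-4.95, adjusted p = 0.064).

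In single F6 lines against the mid-parent, the floral genes SEP1 and AP1 were lower in the mimics and higher in Med-F. SEP1 was at -0.70 ± 0.21 (adjusted p = 0.016) in HM-W, -0.73 ± 0.21 (adjusted p = 0.0098) in HM-S, -0.66 ± 0.21 (adjusted p = 0.036) in HM-G, -0.41 (adjusted p = 0.197) in Med-E, 1.13 ± 0.18 in Med-F and 0.75 ± 0.18 (adjusted p = 0.0073) in Sml-D. AP1 was at -0.98 ± 0.35 (adjusted p = 0.045), -0.91 ± 0.35 (adjusted p = 0.0499), -1.41 ± 0.37 (adjusted p = 0.013), -0.49 (adjusted p = 0.385), 1.45 ± 0.29 (adjusted p = 8.1e-04) and 0.84 (adjusted p = 0.064) in the same order. With the clock index in the fit the SEP1 and AP1 calls of the mimics and the SEP1 call of Sml-D (0.65, adjusted p = 0.067) ended. Single libraries ended all 6 mimic calls, and AP1 passed in Sml-D without Ler A (1.03, adjusted p = 0.024). PI rose in Med-F (0.45 ± 0.11, ended without Med-F 1) and lay between -0.23 and -0.03 elsewhere, none called, passing in HM-W without Ler B (-0.30, adjusted p = 0.044). KNAT2 fell in HM-G (-0.62 ± 0.17, adjusted p = 0.014, ended without HM-G 1 or HM-G 3) and passed in Med-F (0.36, adjusted p = 0.102) without Ler A or Med-F 3, with -0.24 to 0.18 in the others. STM was called in no line (-0.79 to 0.57). WUS fell in HM-W (-0.69 ± 0.25, adjusted p = 0.042) and HM-S (-0.66 ± 0.24, adjusted p = 0.039), both calls ending with DESeq2, the clock index, an arithmetic mid-parent and without 6 libraries each, and was at -0.54 to -0.23 in the others.

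Of the remaining genes, HSP22 was called in no line (-0.37 to 0.28). HSP21 fell in Med-E alone (-0.87 ± 0.27, adjusted p = 0.030) and HSP17.6C rose in HM-S alone (1.54 ± 0.49, adjusted p = 0.022), and both calls ended with the clock index, an arithmetic mid-parent and single libraries left out. HSP17.6C passed without Ler C in HM-W (1.55, from 0.75) and HM-G (2.16, from 1.36), and was at -0.88 to -0.72 in the other 3 lines. HSP21 was at -0.58 to -0.06 outside Med-E. LHCB6 fell in HM-W (-0.47 ± 0.14, adjusted p = 0.014) and HM-S (-0.65 ± 0.14, adjusted p = 0.0012), both ended by the clock index, and LHCB3 (-0.42 ± 0.13) and PSAD1 (-0.30 ± 0.09) fell in Med-F, ended by the clock index or without Med-F 3. The HM-W call of LHCB6 ended without HM-W 2 as well (-0.30, adjusted p = 0.155). LHCB6 in Med-F (-0.36, adjusted p = 0.057) was called by DESeq2 and with the stricter filter. LHCB3 was at 0.04 in Med-E and -0.15 in Sml-D, LHCB6 at -0.05, -0.04 and 0.05 in HM-G, Med-E and Sml-D, and PSAD1 at -0.23 to 0.20 in the other 5 lines. ICS1 was called in none (-0.22 to 0.26). PR1 was at -0.06 in HM-W, -0.07 in HM-S, -2.24 ± 1.09 in HM-G, -1.20 in Med-E and -3.07 ± 1.16 (adjusted p = 0.057) in Med-F, and PR1 in HM-G versus mid-parent passed without HM-G 2 (-4.76, adjusted p = 0.047) and in Med-F with DESeq2 (adjusted p = 0.023) and the stricter filter. FLC rose by 1.89, 1.59, 1.44 and 2.53 in HM-W, HM-S, HM-G and Med-E and fell by -1.28 and -1.31 in Med-F and Sml-D. TGG2 was at 2.87, 2.49, 2.90, -2.47, 3.00 and 3.51, AOP2 at 2.56, 2.85, 2.76, 4.26, -4.97 and -4.24 and AOP3 at -3.93, -3.69, -3.92, -3.94, 2.82 and 4.26, all called. Against the arithmetic mid-parent FLC and AOP2 turned in the 3 mimics and TGG2 in HM-S, and the calls of FLC in Med-E, TGG2 in HM-W, HM-G and Med-F and AOP3 in Med-F ended.

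The numbers of genes above and below the mid-parent were 3674 and 3553 in HM-W, 4432 and 4207 in HM-S, 2114 and 1804 in HM-G, 2196 and 2066 in Med-E, 3761 and 2888 in Med-F and 1970 and 1865 in Sml-D. Between 35.4% (HM-S) and 60.0% (HM-G) of these calls lay at genes that differed between the parents. With the clock index in the fit the totals were 1378 for HM-W, 2629 for HM-S, 2189 for HM-G, 1821 for Med-E, 4276 for Med-F and 2221 for Sml-D. Leaving out 1 sibling of the line lowered HM-W versus mid-parent to 4640 (HM-W 2), HM-G versus mid-parent to 2177 (HM-G 2), Med-E versus mid-parent to 2451 (Med-E 2), Med-F versus mid-parent to 3412 (Med-F 1) and Sml-D versus mid-parent to 2445 (Sml-D 2). Sml-D had more genes below than above an arithmetic mid-parent, 1451 against 1009.

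Against the mean of the 2 F1 hybrids PIF4 and IAA29 were not called in the mimics and were lower in the other F6 lines. PIF4 was at -0.07 in HM-W, -0.25 (adjusted p = 0.178) in HM-S and -0.11 in HM-G, and fell by -1.05 ± 0.12 in Med-E, -0.32 ± 0.12 in Med-F and -1.03 ± 0.12 in Sml-D. IAA29 was at 0.44 (adjusted p = 0.241), 0.53 (adjusted p = 0.146) and 0.51 (adjusted p = 0.131) in the mimics and fell by -3.03 ± 0.29, -1.50 ± 0.26 and -1.71 ± 0.26 in the others. YUC8 was higher in HM-S (0.83 ± 0.24, adjusted p = 0.024), was at 0.60 (adjusted p = 0.116) in HM-W and 0.65 (adjusted p = 0.0665) in HM-G, and fell by -1.23 ± 0.28 in Med-E, -0.79 ± 0.26 in Med-F and -0.79 ± 0.26 in Sml-D. Genes higher and lower than in the F1 were 1283 and 1916 in HM-W, 1462 and 1933 in HM-S, 2417 and 2594 in HM-G, 3995 and 4378 in Med-E, 4187 and 3895 in Med-F and 4017 and 4372 in Sml-D. With the clock index in the fit the totals were 1973 in HM-W, 2633 in HM-S, 5857 in HM-G, 1304 in Med-E, 8633 in Med-F and 1727 in Sml-D, so Med-E and Sml-D then had fewer than any mimic. Without HM-W 3 HM-W versus F1 gave 1787, without HM-S 2 HM-S versus F1 gave 2155, without HM-G 2 HM-G versus F1 gave 2608 and without Med-F 1 Med-F versus F1 gave 5141, and with only the compared lines in the fit HM-W, HM-S and Med-F gave 1854, 1485 and 4395.

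Against the F1, calls within the lists were counted without a list test, and several lists had members called in more than 1 line. HM-W was lower at 14 of 24 dehydration genes (18 over the list alone), COR15A by -1.19 ± 0.15, with 0 higher, and HM-S at 9 (14 alone) with 0, Med-F at 11 (16) with 2 (3) and Sml-D at 10 (12) with 1 (1) higher. HM-S was lower at 5 of 32 photosynthesis genes (6 alone), LHCB1.2 (a close copy of its neighbours) by -0.69 ± 0.14, with 0 higher. HM-G was lower at 11 of 18 flavonoid genes (13 alone), DFR by -2.03 ± 0.58, and higher at 8 of 12 heat-shock genes (9 alone), HSP90.1 by 2.94 ± 0.47, as were HM-W at 4 (7 alone) and HM-S at 6 (8 alone). Med-E differed at 17 of 20 circadian genes on both counts, 10 higher, PRR9 by 2.31 ± 0.39 and LUX by -1.57 ± 0.17, and at 14 of 23 cell-wall genes, 4 higher (19 and 7 alone). Sml-D differed at 15 of 20 circadian genes on both counts and was higher at 12 of 18 flavonoid genes (16 alone). Genes of the circadian list also make up the clock index, which was lowest in these 2 lines (-2.07 and -1.86). Med-F was higher at all 8 floral organ genes and Sml-D at 6 on both counts. Med-F was lower at 17 of 27 glucosinolate genes with 1 higher (18 and 1 alone), and Med-E at 5 with 12. PR1 was higher than in the F1 in HM-W (3.19 ± 0.96, adjusted p = 0.033) and HM-S (3.19 ± 0.96, adjusted p = 0.032), but siblings disagreed: PR1 was at 11.8, 70.7 and 59.4 in HM-W and 70.7, 0.22 and 70.8 in HM-S, beside 1.73 to 11.2 in the 6 F1 libraries, so HM-S 2 lay below each of them.

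Some genes lay outside the range of both parents. The F1 had 276 genes above and 243 below both parents, HM-W 874 and 1089, HM-S 1366 and 1576, HM-G 254 and 272, Med-E 371 and 535, Med-F 1051 and 775 and Sml-D 263 and 326. CYP71B22 was above both parents in the mean F1 (1.77 over the mid-parent), HM-W (2.50), HM-S (3.18) and HM-G (2.07). It was at 11.7 in C24XLer, 34.8 in LerXC24 and 9.35 in C24. Also above both in these were AT2G16140 (1.22 in the F1), J20 (0.58) and WAT1 (0.34). The starch-debranching gene DBE1 (-0.48) and AT4G08570 (-1.15) were below both. In all 15 genes were above and 8 below both parents in the F1 and all 3 mimics. With the clock index in the fit the totals were 160 in the F1, 185 in HM-W, 362 in HM-S, 218 in HM-G, 292 in Med-E, 792 in Med-F and 227 in Sml-D. Single libraries moved them too. The total of F1 outside the parental range was 194 without C24 B and 1144 without C24XLer A, that of HM-W outside the parental range 1065 without HM-W 2, and those of HM-S and HM-G 1921 and 239 without C24 A, with 861 in HM-G without C24 C. The total of Med-E outside the parental range was 490 without Med-E 2, that of Med-F outside the parental range 730 without Med-F 1 and 2835 without Med-F 2, and that of Sml-D 329 without Sml-D 2. With only the compared lines in the fit the F1 gave 298 and Med-F 947.

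**Figure D3:**
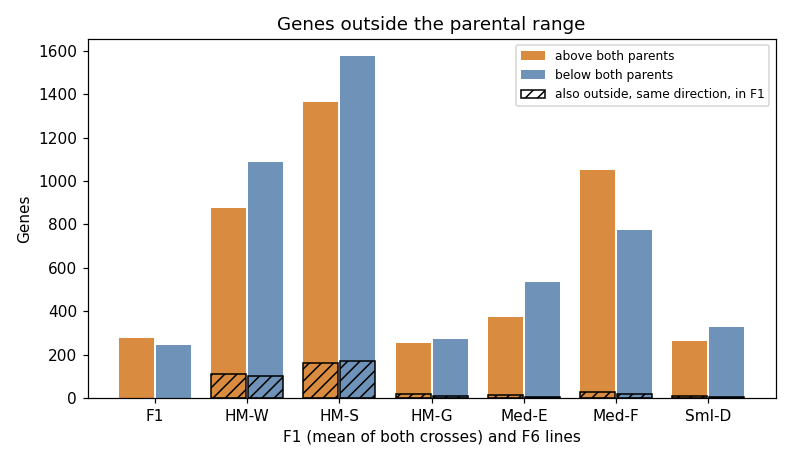
Genes above and below both parents in the F1 and the 6 F6 lines. HM-S had the most (1366 above and 1576 below) and the F1 519.

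Of the 519 genes outside the parental range in the F1, 214 were outside on the same side in HM-W (41.2%), 334 in HM-S (64.4%), 30 in HM-G (5.78%), 20 in Med-E, 44 in Med-F and 10 in Sml-D. Lists drawn independently would share 17.3, 26.0, 4.65, 7.94, 16.3 and 5.19 genes. The same 3 C24 and 3 Ler libraries enter both sides. Simulated data shared at most 1 gene, but held no change outside the parents, so they cannot show what parental noise adds here. The covariance of the log2 changes was 0.0774 in HM-W, 0.0934 in HM-S, 0.0369 in HM-G, -0.00236 in Med-E, 0.0309 in Med-F and -7.2e-04 in Sml-D, beside 0.0151 to 0.0153 in the simulations. The correlation was 0.429, 0.514, 0.230, -0.0150, 0.176 and -0.00458 in the same order, beside 0.419 to 0.429 in the simulations, and a difference of correlations does not estimate the shared part. With separate parental libraries on the 2 sides, a test chosen after these values were seen, the covariance of log2 CPM averaged 0.0528, 0.0613, 0.0182, -0.0168, 0.0106 and -0.0153 over 18 divisions, and all 18 were above 0 only in HM-W (lowest 0.0253) and HM-S (0.0360). Genes outside on opposite sides numbered 15 for Med-E, 18 for Med-F, 6 for Sml-D, 1 for HM-G and 0 for HM-W and HM-S. With the clock index in the fit the shared genes were 19, 33, 5, 4, 11 and 1 in the same order of lines. Without C24 B, 90 genes were shared with HM-W, and without C24XLer A 432. In the overlap of F6 lines with F1, HM-S gave 131 and 717 without these libraries. HM-G shared 7 without C24 A and 88 without C24 C, Med-E 8 without C24 C, Med-F 9 without C24 A and 140 without C24XLer A, and Sml-D 2 without C24 B and 21 without C24XLer A.

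The F6 lines carried parental expression levels in blocks. Of 324 genes with very different parental levels, 56.5% were at the C24 level in HM-W, 41.05% in HM-S, 54.9% in HM-G, 40.7% in Med-E, 33.02% in Med-F and 44.4% in Sml-D, and in HM-S 25.3% were in between. On chromosome 1 4.05% of these genes were at the C24 level in HM-W and 6.76% in HM-S but 85.1% in Med-E. FLC was at 53.0 ± 8.1 in Med-E, 24.9 to 34.0 in the mimics and 3.78 ± 0.83 and 3.70 ± 0.97 in Med-F and Sml-D. Where both lines could be classed from neighbouring genes, HM-S and HM-G carried the same parent at 88.1% of genes, Med-F and Sml-D at 78.8%, HM-W and HM-S at 69.5% and HM-W and Med-E at 12.2%, and with a second setting of the classes, chosen after the first had been seen, at 82.6%, 80.1%, 61.9% and 17.63%.

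**Figure D4:**
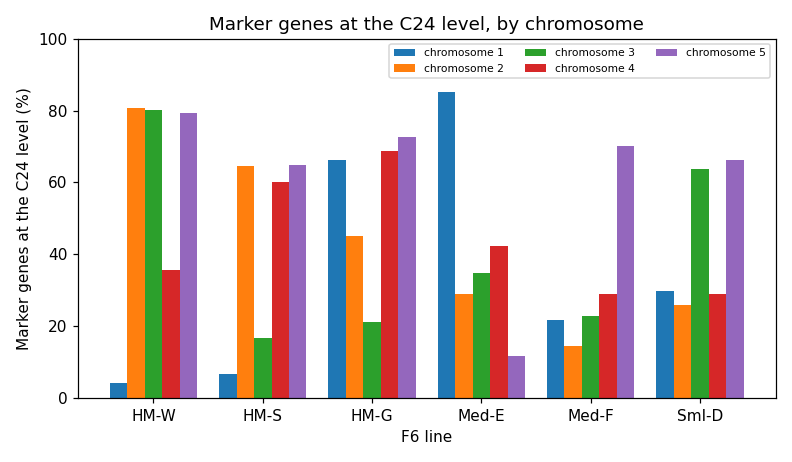
Parental level of the 324 marker genes along the 5 chromosomes in the 6 F6 lines. The C24 level was found for 56.5% in HM-W and 33.02% in Med-F.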

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

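The tests of harvest time and of the parental allele for YUC8 and IAA29, the tests of shared parental segments and of the spacing of calls, the clock index as a covariate and all splits except those of single F6 lines against the F1 were chosen only after the results were seen.

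The difference in YUC8 (1.62) and IAA29 (2.43) between the mimics and the other F6 lines passed a test of the difference itself between the 2 groups of lines. Harvest time may add to it, since YUC8 followed the clock index within lines, and stays open as a cause. IAA29 still differed by 2.01 between HM-G and Med-F, of similar index, but 1 pair cannot decide. IAA29 lay above both parents in 3 of 3 mimics, but at higher indices, so a parental allele there stays open. With the index as a covariate of the 6 lines YUC8 went from 1.62 ± 0.16 to 1.44 ± 0.25. IAA29 went from 2.43 ± 0.37 to 1.89 ± 0.51. Both calls ended as residual degrees of freedom went from 4 to 3, standard errors rose and changes shrank. PIF4 fell from 0.62 ± 0.21 to 0.16 ± 0.16. With the index in the fit of 30 libraries, whose error is from siblings, YUC8 was at 0.74 and IAA29 at 2.00. Alleles at other loci and an altered clock in the mimics were not tested and stay open.

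The crosses C24XLer and LerXC24 differed at 1439 genes in a direct test, and LerXC24 had more calls against the mid-parent (4820 beside 685). With the clock index in the fit this order turned, to 159 for LerXC24 and 1020 for C24XLer. Across 29268 genes LerXC24 minus C24XLer correlated at 0.555 with the slope on the clock index in the other 8 lines (p = 0.032 over 1000 permutations of the index within lines, highest 0.612, Spearman 0.470), a result consistent with a later harvest of some LerXC24 libraries. Library size as the cause is argued against: the count totals of LerXC24 were 1.104 times those of C24XLer, a ratio between the bounds set for either outcome, but with its libraries thinned to the same size LerXC24 still gave 4777 calls beside 680 for C24XLer. The direction of the cross itself was not tested apart from harvest and stays open. For C24XLer versus LerXC24 with the 6 hybrid libraries alone in the fit edgeR called 0 genes, with 3917 unadjusted.

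Genes called between the mimics and the other F6 lines lay together on the chromosomes: 203 of 444 had another call within 10 tested genes, beside 115 on average and at most 153 in 1000 random draws (permutation p = 9.99e-04), and 152 of 353 beside 94.0 without overlapping genes. Parental segments shared by the mimics are a candidate explanation for part of this. Segments were read from the expression of marker genes, which then differ between the groups by construction, so markers and overlapping genes were left out. Where the 3 mimics carried 1 parent and the other 3 lines the other, 8 of 22 classed calls lay among 70 of 2027 genes, an odds ratio of 17.8 (Fisher's exact p = 2.9e-07), and 7 of 7 with a parental difference went in the parental direction. In the second setting 31 of 56 calls lay among 592 of 4812 genes, an odds ratio of 9.26 (Fisher's exact p = 8.3e-15), and 19 of 21 went that way. Neighbouring genes inherited together are not independent, so these p-values are too small. The calls outside such segments, those that could not be classed, and other reasons for nearby calls, such as gene copies side by side, stay open.

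The libraries of each comparison were also regrouped (splits) and fitted alone. Of 40 splits each, the real one alone gave as many calls for LerXC24 (3767, highest other 570) and the mean F1 (1845 and 116) against the mid-parent and for the F1 outside the parental range (298 and 0). The same held (1 of 40) against the mid-parent for HM-W (6555 and 2402), HM-S (7786 and 2259), HM-G (4229 and 1962), Med-F (4608 and 2739) and Sml-D (3737 and 3553), and outside the range for HM-W (1682 and 1197) and HM-S (2686 and 374). It held against the F1 for HM-W (1854 and 1401), HM-S (1485 and 0), HM-G (3566 and 1070), Med-E (6304 and 2324), Med-F (4395 and 3341) and Sml-D (6144 and 4249).

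In other comparisons at least 2 of 40 splits gave as many calls. These were C24XLer against the mid-parent (3 splits, 290 and 1800), Med-E against it (2 splits, 3841 and 3858), and outside the range HM-G (2 splits, 579 and 1053), Med-E (2 splits, 754 and 1775), Med-F (3 splits, 947 and 1331) and Sml-D (3 splits, 587 and 1721). The splits mix libraries of different lines, whose differences enter each split, so neither outcome decides on chance. The 10 splits of 3 against 3 are too few for a share under 0.05: the real split gave 6492 for C24 against Ler (1 of 10, highest other 4), 0 for the reciprocal crosses (10 of 10, highest other 0) and 444 for the mimics against the other F6 lines (1 of 10, highest other 10).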

How the results depend on the processing

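The clock index as a covariate, the thinned libraries and the second setting of the parental classes were chosen only after the results were seen, and the other settings in this part were planned. Each comparison rests on 3 libraries per line or on 3 lines a side, and where a count moved the cause was not tested.

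RLE factors left all 226 values of named genes on the same side of the threshold, and so did running without a filter for 225 of 226. The stricter filter kept the call of 180 of 183 and brought 3 past the threshold, and it gave no value for 43. DESeq2 kept 212 of 225, ended 2 and added 11, and gave no value for 1. It called 1158 genes (848 up and 310 down) for C24XLer versus mid-parent and 2965 (1478 and 1487) for HM lines versus other F6 lines, and no other count moved over 1.5 times. With the compared lines alone in the fit the counts fell to 290 for C24XLer, 1845 for the mean F1, 298 for the F1 outside the parental range and 947 for Med-F outside it. Against the F1 they fell to 1854 in HM-W, 1485 in HM-S and 4395 in Med-F. For C24XLer versus LerXC24 edgeR then called 0 genes, with 3917 at an unadjusted p under 0.05.

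The arithmetic mid-parent kept 126 of 164 gene values, ended 29 calls and turned 9. Its counts were 13 for C24XLer versus mid-parent (2 up and 11 down, with 3467 unadjusted), 2488 for LerXC24 versus mid-parent, 371 for the mean F1, 2551 for HM-G versus mid-parent and 2460 for Sml-D versus mid-parent. The values that turned were TGG2 (-0.082) and AOP2 (-0.77) in the F1, AOP2 (-0.53) and FLC (-0.47) in HM-W, TGG2 (-0.27), AOP2 (-0.24) and FLC (-0.76) in HM-S, and AOP2 (-0.33) and FLC (-0.92) in HM-G. A mean of logs lies below the log of a mean, and most at genes that 1 parent hardly expresses, which these 3 are.

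The clock index kept 165 of 226 gene values, ended 47 calls, added 2 and turned 12. The counts with it were 159 for LerXC24 (147 up and 12 down), 1020 for C24XLer (783 and 237), 1131 for the mean F1, 1378 for HM-W, 2629 for HM-S, 2189 for HM-G, 1821 for Med-E, 4276 for Med-F and 2221 for Sml-D against the mid-parent, and 0 between the reciprocal crosses (841 unadjusted). Against the F1 they were 1973 for HM-W, 2633 for HM-S, 5857 for HM-G, 1304 for Med-E, 8633 for Med-F and 1727 for Sml-D. Outside the parental range they were 160 for the F1, 185 for HM-W, 362 for HM-S, 218 for HM-G, 292 for Med-E and 227 for Sml-D, and Med-F outside the parental range gave 792. Shared with the F1 were 19 in HM-W, 33 in HM-S, 5 in HM-G, 4 in Med-E, 11 in Med-F and 1 in Sml-D. The mimics against the other F6 lines gave 53 (18 up and 35 down). The values that turned, none of them called with the index, were YUC8 in C24 against Ler (-0.57), in Med-E (0.13) and in Sml-D (0.42), PIF4 in HM-W (-0.082), HM-S (-0.23) and Med-F (-0.19), LHCB6 in HM-G (0.016) and Sml-D (-0.023), LHCB3 in Med-E (-0.064), ICS1 in Med-F (0.084), and HSP22 (-0.010) and HSP21 (0.090) in Sml-D.

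With the 18 siblings as replicates HM lines versus other F6 lines gave 8716 calls (4396 up and 4320 down), and 8037 (4057 and 3980) with the sibling number as a block. These fits treat siblings of a line as separate samples of their group, and of the 32 gene values 24 kept their side and 8 passed in both. A replicate block of the letters A, B and C on the 12 parent and F1 libraries gave 6932 calls for C24 versus Ler, 476 for C24XLer, 4319 for LerXC24 versus mid-parent, 2771 for F1 versus mid-parent, 1423 for C24XLer versus LerXC24 and 469 for the F1 outside the parental range, and no count moved over 1.5 times. Whether the letters pair the samples stays open: in the parents and F1 the correlations of 18 pairs ran from -0.083 to 0.311, with 7 over 0.1 and 8 of 12 libraries closest to their own letter where 4 are expected, and the clock index was lower in A (-1.42, -1.89, -1.18 and -0.73 in C24, Ler, C24XLer and LerXC24) than in C (0.05, -1.34, -0.75 and 0.64). Among siblings 45 pairs ran from -0.243 to 0.178, with 4 over 0.1 and 3 of 18 libraries closest to their own number.

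With an estimated correlation 0 of 253 list tests passed, against 58 with the preset value and 62 with fry. With bounds of 0.33 and 0.67 the share of genes at the C24 level was 58.3% in HM-W and HM-G, 42.9% in Med-E and 36.1% in Med-F. With a marker minimum of 2 it was 48.1% in HM-W, 37.0% in Med-E, 34.1% in Med-F and 41.6% in Sml-D.

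Leaving out 1 library, or 1 line for the mimics, kept 1739 of 1944 gene values, ended 145 calls, added 22 and turned 38. The range of counts was 256 (without C24XLer B) to 2007 (C24XLer A) for C24XLer versus mid-parent, 1307 (LerXC24 C) to 5569 (C24 C) for LerXC24 versus mid-parent, 1888 (C24XLer B) to 4964 (C24XLer A) for F1 versus mid-parent, 4640 (HM-W 2) to 7571 (C24 C) for HM-W versus mid-parent, 2177 (HM-G 2) to 4586 (C24 C) for HM-G versus mid-parent, 2451 (Med-E 2) to 4639 (C24 A) for Med-E versus mid-parent, 3412 (Med-F 1) to 7299 (Med-F 2) for Med-F versus mid-parent and 2445 (Sml-D 2) to 4370 (C24 A) for Sml-D versus mid-parent. For C24XLer versus LerXC24 it was 0 (LerXC24 C) to 2944 (LerXC24 A). It was 1787 (HM-W 3) to 3600 (C24XLer C) for HM-W versus F1, 2155 (HM-S 2) to 3903 (C24XLer C) for HM-S versus F1, 2608 (HM-G 2) to 5757 (C24XLer A) for HM-G versus F1 and 5141 (Med-F 1) to 8224 (Med-F 2) for Med-F versus F1. HM lines versus other F6 lines gave 33 (without HM-S) to 2373 (without Med-F).

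The counts were 194 (without C24 B) to 1144 (C24XLer A) for F1 outside the parental range, 1065 (HM-W 2) to 2296 (C24 C) for HM-W outside the parental range, 1921 (C24 A) to 3129 (C24 C) for HM-S outside the parental range and 239 (C24 A) to 861 (C24 C) for HM-G. They were 490 (Med-E 2) to 1024 (C24 A) for Med-E outside the parental range, 730 (Med-F 1) to 2835 (Med-F 2) for Med-F outside the parental range and 329 (Sml-D 2) to 713 (C24 A) for Sml-D outside the parental range. In the overlap of F6 lines with F1, HM-S ran from 131 to 717 and HM-W from 90 to 432 (both C24 B and C24XLer A). The others ran from 7 (C24 A) to 88 (C24 C) in HM-G, 8 (C24 C) to 27 (C24XLer A) in Med-E, 9 (C24 A) to 140 (C24XLer A) in Med-F and 2 (C24 B) to 21 (C24XLer A) in Sml-D.

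The gene values that crossed 0 when a library was left out were all uncalled. They ran from -0.26 to 0.45 for YUC8 in C24 against Ler, and against the mid-parent in HM-W from -0.47 to 0.40 for PR1, -0.46 to 0.055 for HSP22 and -0.039 to 0.13 for PSAD1. In HM-S they were -0.15 to 0.0042 (PI), -0.18 to 0.065 (KNAT2), -0.48 to 0.52 (PR1), -0.31 to 0.27 (HSP21) and -0.048 to 0.62 (HSP22), and in HM-G -0.015 to 0.069 (LHCB3). In Med-E they were -0.37 to 0.15 (HSP22), -0.050 to 0.084 (LHCB3), -0.29 to 0.0034 (STM) and -0.13 to 0.013 (LHCB6), and in Med-F -0.052 to 0.11 (PIF4), -0.19 to 0.058 (ICS1), -0.28 to 0.089 (YUC8) and -0.12 to 0.40 (HSP22). In Sml-D they were -0.12 to 0.023 (HSP21), -0.28 to 0.090 (YUC8), -0.11 to 0.044 (PI), -0.089 to 0.48 (HSP22) and -0.95 to 0.085 (HSP17.6C), and for ICS1 in the mimics against the other F6 lines -0.15 to 0.029.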

Other observations

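The genes in this part were singled out, and all of its comparisons made, after the results were seen. Of the 5 largest falls, AT1G50290 was the one called below both parents in all 3 mimics. It was at 1.46 ± 0.06, 1.40 ± 0.14 and 1.43 ± 0.37 CPM in HM-W, HM-S and HM-G, at 48.6 ± 5.2 in C24 and 28.8 ± 1.7 in Ler, and near the parents in the F1 (36.5 ± 1.3 and 37.0 ± 2.8). In the other F6 lines it was at 84.9 ± 7.6 in Med-E, above both parents, 52.4 ± 25 in Med-F and 39.4 ± 4.3 in Sml-D. The 5 counted genes on each side of it did not differ between mimics and other F6 lines, from AT1G50260 (-0.32, adjusted p = 0.140) to AT1G50310 (0.34, adjusted p = 0.305). The edgeR call (-5.35 ± 0.32, adjusted p = 0.0025) stayed under each alternative run, with adjusted p up to 0.035 without HM-S. Neither parent had so low a level, and no cause was tested.

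The neighbouring immune receptor genes DAR4 and CSA1 lay at parental levels in the F6 lines. DAR4 was at 2.62, 2.15 and 2.52 in HM-W, HM-S and HM-G beside 2.70 in Ler, and at 53.9, 47.3 and 41.2 in Med-E, Med-F and Sml-D beside 39.1 in C24. CSA1 was at 4.46, 4.36 and 3.46 beside 3.34 in Ler, and at 62.2, 68.0 and 61.5 beside 66.3 in C24. They lie a little beyond the last classed gene, AT5G17460, of the chromosome 5 segment in which the mimics carried Ler and the other lines C24, a segment with 20 calls among 549 genes. The 2 other segments with calls ran from AT1G17200 to AT1G19070 (12 calls among 209 genes) and from AT2G14290 to AT2G15170 (14 among 74), and the latter holds RLP18, AT2G15042 and PR1.

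The siblings of HM-S were less alike than those of the other lines at the parental markers. The share at the C24 level, computed per sibling, was 44.9% with an SD of 5.28 in HM-S, and the SD was 0.617 in HM-G, 0.777 in HM-W, 0.471 in Med-E, 0.992 in Med-F and 1.96 in Sml-D. HM-S also had 25.3% of markers between the bounds. No test of this difference was made, and the glucosinolate gene ESM1 was not used here because the table has no entry for it.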
